A study of Homo sapiens with 4 samples.

How the data were processed

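Messenger RNA of A673 cells was measured by RNA-seq in 4 libraries, 2 from cells given DMSO and 2 from cells given CBL0137 at 1 µM, both for 24 h. Total RNA was isolated with TRIzol and libraries were made by an Illumina protocol, per the labels' protocols. Whether the libraries kept strand, and whether RNA was selected by its poly(A) tail, is not given in the sources used here, so reads of overlapping or antisense genes may not be told apart.

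Per the submitters' processing notes, the authors trimmed adapters with Trim Galore, mapped reads to hg19 with HISAT2, and made the deposited gene counts with HTSeq 0.11.1. The processing notes also name DESeq2 1.26.0, and a further genome build of another species, whose use for these human libraries is not given in the sources used here. The deposited table also holds FPKM per gene and library, which per the labels the authors computed from the mapped reads, the gene length and the sequencing depth, with a tool that is not given in the sources used here. The annotation release behind the counts is not given in the sources used here.

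The table has 60623 rows, of which 60617 name a gene. The other 6 are the 5 HTSeq summary rows and 1 leftover header row. Reads in the summary rows made up 23.9% and 24.1% of all reads in DMSO replicates 1 and 2, and 23.7% and 24.8% in CBL0137 replicates 1 and 2, and they stayed out of library sizes and tests. Counts over genes ran from 20483714 to 23373554 per library. Ensembl IDs were matched to symbols and GRCh37 positions in GENCODE release 44 lifted to GRCh37 (the build also called hg19), which named 58524 of them, and 2093 stayed without a name. SOD2, BOP1 and H2BC8 of the gene lists had no matching ID.

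Groups came from the sample titles. The main test was edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, filterByExpr by group at its minimum count of 10, and the quasi-likelihood test of CBL0137 against DMSO with no further term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold change above 1.5, the limits in the series' own description. Expression is given as CPM after TMM scaling, except where the text says that CPM is over all gene counts without it. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. The common biological coefficient of variation was 3.18%. Intervals from 2 libraries per group are wide for weakly expressed genes, and depth limits what can be called there.

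Before the data were examined, 21 gene lists were fixed, namely FACT and histone chaperones, EWS-FLI1 activated and repressed targets, p53, NF-kB, interferon-stimulated, heat shock, histone, G2/M, G1/S, ribosome biogenesis, DNA repair, unfolded protein and integrated stress response, apoptosis, cholesterol synthesis, lysosome and immediate early genes, epithelial, blood and neuronal markers, and mitochondrially encoded genes as a sign of RNA quality. Each was tested against the other genes with limma 3.58.1 camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and also with a correlation estimated from the data and with fry, which asks whether a list's genes move on balance one way. The 12 calls of camera were all lost with the estimated correlation, and each such p is given beside its list. That setting takes its degrees of freedom from the 4 libraries, so such a loss was likely even for a list with little correlation. Genes are named by a rule fixed at the same time. It takes SSRP1, SUPT16H, EWSR1, FLI1 and MYC, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and conditions that do not overlap, and up to 4 members of each list with the smallest adjusted p. Genes named outside this rule were chosen after their values were seen, and the text says so. Some genes that the rule takes are not reported here.

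The test was tried on simulated data first, with 200 genes set to change in counts drawn from these libraries' means and dispersions. Of 16898 genes that passed the filter, it called 75 of 96 genes changed 2-fold, 65 of 96 changed 1.6-fold and 3 of 16706 unchanged genes. Camera recovered a simulated fall of the G2/M list and called 0 of the 20 other lists. Each gene was drawn independently there, so the simulation cannot show how often correlation between genes makes camera call a list wrongly.

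Alternatives fixed beforehand were RLE and upper-quartile factors, library size alone, no count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, other fold limits, glmTreat, each replicate left out, the replicate number as a block, and limma-trend on log2(FPKM + 1) for genes with an FPKM of at least 1 in 2 libraries. With a replicate left out, the lone library of its group is assumed to vary like the other group. Removal of the abundance trend from the list test was added after the data were seen. Tables were prepared with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.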

Results

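Messenger RNA was profiled in A673, a human Ewing sarcoma cell line whose driver is a fusion of EWSR1 to FLI1 and which lacks functional p53. Cells received CBL0137 at 1 µM or DMSO, its solvent, for 24 h. CBL0137 is a curaxin, a DNA-binding small molecule that traps on chromatin the histone chaperone FACT, made of SSRP1 and SUPT16H. Each condition had 2 libraries. The reads assigned to genes numbered 23373554 and 23031963 in DMSO replicates 1 and 2, and 20483714 and 22817617 in CBL0137 replicates 1 and 2. Mitochondrially encoded transcripts took 5.87%, 5.88%, 5.92% and 5.82% of these counts in the same order. Replicates within a condition differed by more than sampling noise, with a chi-square per degree of freedom of 2.02 in DMSO and 2.47 in CBL0137, against 18.5 between DMSO replicate 1 and CBL0137 replicate 1. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

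The comparison asked which transcripts change when A673 cells are exposed to a FACT-targeting compound. After 24 h of CBL0137, genes of mitosis, DNA replication, cholesterol synthesis and the integrated stress response were among those that fell, and histone genes, COL6A3, and the NF-kB targets ICAM1 and CCL2 were among those that rose. AURKB, a mitotic kinase, fell from 135 ± 2.87 to 68.7 ± 2.80 CPM, and HMGCS1, an early enzyme of cholesterol synthesis, fell from 146 ± 1.67 to 74.9 ± 0.830 CPM (mean ± SD, n = 2 per condition here and below). H2BC5, a histone H2B gene, rose from 11.9 ± 1.62 to 35.8 ± 0.721 CPM. COL6A3, a chain of the matrix protein collagen VI, rose from 17.9 ± 1.25 to 74.8 ± 2.89 CPM. Of 17309 genes tested with edgeR's quasi-likelihood test, 1663 passed a Benjamini-Hochberg adjusted p of 0.05 with a fold change above 1.5, and 1191 of these were higher and 472 lower in CBL0137. DESeq2, the tool named by the submitters, called 919 genes at the same limits, 593 higher and 326 lower, and 909 of them were among the 1663. On libraries simulated from these samples, the same test called 78.1% of genes changed 2-fold and 67.7% of those changed 1.6-fold, so some changed genes would be missed with 2 libraries per condition.

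**Figure D1:**
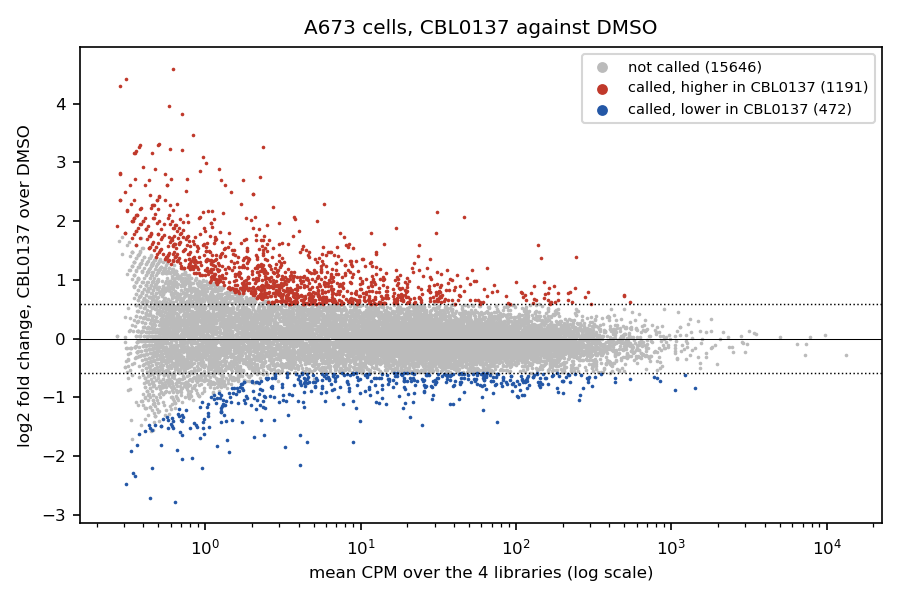
Log2 fold change of CBL0137 over DMSO against mean CPM over the 4 libraries (log scale), 1 point per tested gene, with dotted lines at a 1.5-fold change. The 1191 genes called higher (red) lie more toward low CPM than the 472 called lower (blue), and 15646 genes were not called (grey).

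Neither subunit of FACT was called at the transcript level. SSRP1 (ENSG00000149136, chromosome 11, 57093460 to 57103366 in GRCh37) measured 555 ± 8.31 CPM in DMSO and 448 ± 1.32 in CBL0137, a log2 fold change of -0.31 ± 0.03 (SE) with an edgeR adjusted p of 3.5e-08 (Benjamini-Hochberg), below the fold limit. SUPT16H (ENSG00000092201, chromosome 14, 21819635 to 21852178) measured 406 ± 4.65 and 395 ± 0.763 CPM, with a log2 fold change of -0.04 ± 0.03 and an edgeR adjusted p of 0.41, and its sign turned under upper-quartile factors (0.01) and under library size alone (0.02). Of the 15 FACT and histone chaperone genes, 2 fell, 0 rose and 13 were not called, and adjusted over the list alone 2 fell. The members that fell were HJURP, which loads the centromeric histone CENP-A (-0.96 ± 0.05), and ASF1B, a histone H3-H4 chaperone of proliferating cells (-0.60 ± 0.06). ASF1B lost its call under upper-quartile factors (-0.55), library size alone (-0.53) and a filter of 1 CPM (-0.58), and without DMSO replicate 1 (-0.57) or CBL0137 replicate 2 (-0.54). Camera called the list lower (adjusted p = 0.00333; adjusted p = 0.366 with an estimated correlation), and the call was also lost with the abundance trend removed (0.172).

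Transcripts of the fusion partners were not called. EWSR1 (chromosome 22, 29663998 to 29696515) had a log2 fold change of -0.19 ± 0.04, and FLI1 (chromosome 11, 128556430 to 128683162) of 0.04 ± 0.06, with edgeR adjusted p of 1.5e-04 and 0.63. Reads from the fusion transcript can count toward either gene, and the sign of FLI1 turned without DMSO replicate 2 (-0.03). The deposited FPKM of FLI1 was 2.79 in CBL0137 replicate 2 against 10.4 to 11.8 in the other libraries, while its counts were 1618 there and 1459 to 1614 in the others. Of 34 tested genes known to be activated by EWS-FLI1, 3 rose, 1 fell and 30 were not called, with the same counts adjusted over the list alone. LOXHD1 fell (-0.82 ± 0.06), while GLI1 (0.60), CCK (1.46) and UPP1 (0.70) rose; NR0B1 (0.29 ± 0.04), ID2 (0.38 ± 0.04) and KDSR (0.35 ± 0.04) stayed below the fold limit. Of 23 tested genes known to be repressed by EWS-FLI1, 3 rose, 0 fell and 20 were not called, again with the same counts adjusted over the list alone, while DESeq2 called 2 rises. Those that rose included CDKN1A (0.78 ± 0.05) and SNAI2 (0.72), whereas TNC (0.33 ± 0.04) and COL1A2 (0.19 ± 0.03) were not called. Camera called neither list (adjusted p = 0.568 for activated and 0.107 for repressed genes), although the repressed list passed without CBL0137 replicate 1 (adjusted p = 0.0148) and under library size alone (0.046), with a range of 0.0148 to 0.587 over its alternatives. With the abundance trend removed, a test added after the data were seen, both lists were called higher, at 0.0214 for activated genes (range over alternatives 0.0214 to 0.8) and 0.0269 for repressed genes. GLI1, CCK, UPP1 and SNAI2 were singled out after their values were seen.

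Many genes of the cell division cycle fell. Of 24 G2/M genes, 9 fell, 0 rose and 15 were not called, 9 fell adjusted over the list alone, and 23 had an edgeR adjusted p under 0.05 with a lower level in CBL0137. AURKB (chromosome 17, 8108051 to 8113918) changed by -0.98 ± 0.05, the cyclin-dependent kinase CDK1 by -0.85 ± 0.05, cyclin A2 (CCNA2) by -0.77 ± 0.04 and the proliferation antigen MKI67 by -0.72 ± 0.03 on the log2 scale. Of 28 G1/S and DNA replication genes, 4 fell, 0 rose and 24 were not called, and 4 fell adjusted over the list alone. Both subunits of ribonucleotide reductase, which makes deoxynucleotides, were among them, RRM2 at -1.05 ± 0.04 and RRM1 at -0.62 ± 0.04, and RRM1 dropped below the fold limit under upper-quartile factors (-0.57) and library size alone (-0.56). TYMS (-0.68) and CDC45 (-0.62) also fell, as members noted after their values were seen, whereas PCNA (-0.44 ± 0.04) and MCM7 (-0.39 ± 0.03) stayed inside the fold limit. Of 24 DNA repair genes, 1 fell, 0 rose and 23 were not called, and 1 fell adjusted over the list alone. That gene was RAD51AP1, which acts in homologous recombination (-0.61 ± 0.06), and it lost its call under upper-quartile factors (-0.56), library size alone (-0.55) and without DMSO replicate 2 (-0.58); CHEK2 (-0.48 ± 0.06), FANCA (-0.42 ± 0.05) and FANCI (-0.32 ± 0.04) were not called. Camera placed the G2/M list (median log2 fold change -0.55, adjusted p = 1.4e-48), the G1/S list (-0.31, 1.3e-15) and the repair list (-0.26, 3.6e-05) below the other genes. Those calls were lost when the correlation was estimated from the 4 libraries, with adjusted p = 0.11, 0.21 and 0.305 with an estimated correlation.

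**Figure D2:**
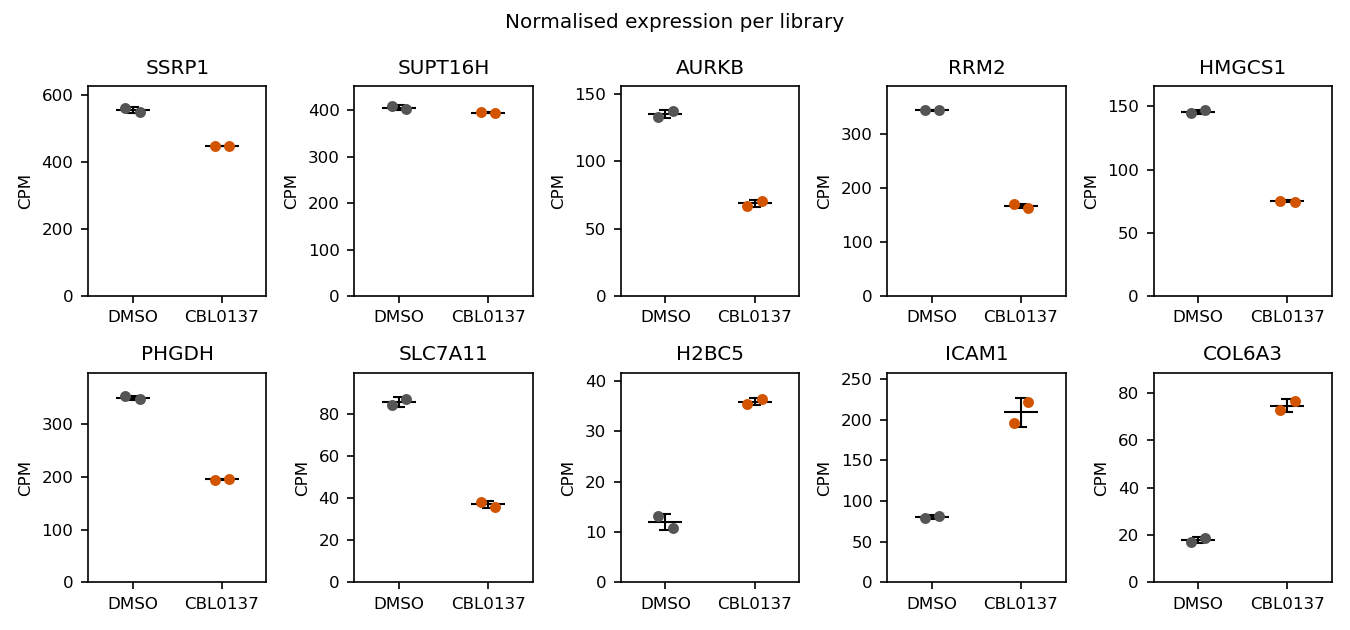
Normalised expression (CPM, linear axes from 0) of 10 genes in each library, with DMSO in grey, CBL0137 in orange, and bars giving the mean ± SD of 2 libraries. The 2 conditions do not overlap for any gene shown, with SSRP1 at 555 and 448 CPM and COL6A3 at 17.9 and 74.8 CPM as examples, and SUPT16H did not pass the test.

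Genes of cholesterol synthesis and of the integrated stress response fell as well. Of 20 cholesterol synthesis genes, 7 fell, 0 rose and 13 were not called, and 7 fell adjusted over the list alone. They included HMGCS1 (chromosome 5, 43287572 to 43313614; -0.96 ± 0.05), INSIG1, a regulator of SREBP processing (-0.77 ± 0.05), and MSMO1, a sterol oxidase (-0.74 ± 0.05). Of 20 unfolded protein and integrated stress response genes, 8 fell, 0 rose and 12 were not called, and 8 fell adjusted over the list alone. ATF4, the transcription factor at the centre of the integrated stress response, fell (-0.66 ± 0.04), as did the serine synthesis enzymes PHGDH (-0.84 ± 0.04) and PSAT1 (-0.85 ± 0.05) and the mTORC1 inhibitor DDIT4 (-0.79 ± 0.08). Camera called both lists lower (median -0.53, adjusted p = 3.8e-26 for cholesterol and -0.37, 1.1e-09 for the stress response), with adjusted p = 0.11 and 0.143 with an estimated correlation.

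Of 16 tested histone genes, 8 rose, 0 fell and 8 were not called, and 9 rose adjusted over the list alone. H2BC5 (1.59 ± 0.09), H2AC6 (1.07 ± 0.07) and the linker histone H1-2 (0.81 ± 0.12), all on chromosome 6, were among those that rose. Clustered histone mRNAs mostly lack a poly(A) tail, and how RNA was selected is not given in the sources used here. The list was called higher (median 0.98, camera adjusted p = 5.1e-11; adjusted p = 0.213 with an estimated correlation).

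Some targets of NF-kB and interferon rose. Of 18 NF-kB targets, 3 rose, 0 fell and 15 were not called, and 3 rose adjusted over the list alone. The adhesion molecule ICAM1 (chromosome 19, 10381769 to 10397291) rose from 80.6 ± 2.33 to 209 ± 18 CPM (1.38 ± 0.05), the chemokine CCL2 changed by 0.81 ± 0.06 and the TNF receptor adaptor TRAF1 by 0.93 ± 0.09, while NFKB2 measured -0.25 ± 0.05. Of 25 interferon-stimulated genes, 5 rose, 0 fell and 20 were not called, and 5 rose adjusted over the list alone, while DESeq2 called 3. Those 5 were OASL (1.47 ± 0.17), IFIT2 (0.96 ± 0.11) and, noted after their values were seen, OAS2 (2.18), IFI27 (0.72) and RSAD2 (0.76); ISG15 (0.50 ± 0.07) stayed inside the fold limit. Camera called both lists higher (adjusted p = 0.00315 for NF-kB and 0.00333 for interferon), with adjusted p = 0.213 and 0.37 with an estimated correlation, and fry gave 0.0591 for interferon. Of 18 immediate early genes, FOSL1 (0.60) and EGR3 (1.33) rose, ATF3 (-0.63) fell and 15 were not called, among them EGR1 (0.58 ± 0.07), IER2 (0.51 ± 0.07), EGR2 (0.36 ± 0.05) and KLF6 (-0.32 ± 0.05). The same 2 rises and 1 fall were counted adjusted over the list alone, DESeq2 called 1 rise and 1 fall, and camera did not call the list (adjusted p = 0.136). FOSL1, EGR3 and ATF3 were singled out after their values were seen, and EGR1 passed the fold limit under upper-quartile factors (0.63), library size alone (0.64) and a filter of 1 CPM (0.60), and without CBL0137 replicate 1 (0.68).

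Called p53 targets went both ways, while the only apoptosis regulator called fell. Of 24 p53 targets, 2 rose, 2 fell and 20 were not called, with the same counts adjusted over the list alone. The cell cycle inhibitor CDKN1A rose (chromosome 6, 36644237 to 36655114; 51.8 ± 1.68 to 89.2 ± 3.44 CPM), as did TP53I3 (1.12, noted after its value was seen), while the pro-apoptotic BBC3 (-1.07 ± 0.20) and the mitochondrial reductase FDXR (-0.68 ± 0.09) fell, and DDB2 (-0.34 ± 0.05) and CCNG1 (-0.29 ± 0.05) were not called. Of 21 apoptosis regulators, BBC3 fell, 0 rose and 20 were not called, with 1 fall adjusted over the list alone; BMF measured 0.58 ± 0.05, PMAIP1 -0.51 ± 0.06 and BIRC5 -0.57 ± 0.05. BMF passed the fold limit under upper-quartile factors (0.62), library size alone (0.64) and a filter of 1 CPM (0.59), and without CBL0137 replicate 1 (0.60), and BIRC5 with no count filter (-0.59) and without DMSO replicate 1 (-0.61) or CBL0137 replicate 1 (-0.67). Camera called neither list (adjusted p = 0.568 and 0.936). Fry, however, called the p53 targets lower (adjusted p = 0.00299, range over alternatives with all 4 libraries 0.00299 to 0.611). The apoptosis list had a median of 0.10 but a mean of -0.003. MYC, at 255 ± 0.431 and 224 ± 10.3 CPM, had a log2 fold change of -0.19 ± 0.04 (edgeR adjusted p = 3.9e-04) and was not called.

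Among 15 heat shock chaperones and 20 lysosome genes, edgeR called 0 at the fold limit, also adjusted over the list alone, and DESeq2 and limma-voom called 0 as well. At an unadjusted p under 0.05 there were 12 chaperones and 13 lysosome genes, and at an adjusted p under 0.05 without the fold limit 8 chaperones were lower and 3 higher, and 10 lysosome genes higher and 2 lower. HSP90AA1 measured -0.43 ± 0.03, DNAJB1 -0.52 ± 0.04, HSPD1 -0.31 ± 0.03 and HSPH1 0.29 ± 0.04. Lysosomal ATP6V0D1 measured 0.32 ± 0.06, TPP1 0.27 ± 0.05 and CTSB 0.22 ± 0.04. Camera called the chaperone list lower (median -0.19, adjusted p = 0.00384; adjusted p = 0.213 with an estimated correlation and 0.172 with the abundance trend removed) and the lysosome list higher (0.14, 0.0119; adjusted p = 0.328 with an estimated correlation). Of 23 ribosome biogenesis genes, RRS1 rose (0.62 ± 0.09), 0 fell and 22 were not called, with 1 rise adjusted over the list alone; FBL measured -0.30 ± 0.04, WDR43 0.31 ± 0.05 and UTP20 0.30 ± 0.05. RRS1 lost its call without DMSO replicate 2 (0.52) and without CBL0137 replicate 1 (0.57), and camera did not call the list (adjusted p = 0.172) except with the abundance trend removed, where it was higher (0.00984, range over alternatives 0.00984 to 0.37).

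Markers of other cell types were measured in the same way. Of 9 tested epithelial markers, 4 rose, 0 fell and 5 were not called, and 5 rose adjusted over the list alone, while DESeq2 called 1. Another 5 markers were below the count filter, with counts in DMSO replicates 1 and 2 and CBL0137 replicates 1 and 2 of 14, 7, 6 and 5 for EPCAM, 3, 8, 2 and 2 for ESRP1, 2, 1, 0 and 4 for CDH1, 1, 0, 2 and 0 for KRT5, and 0 in each for GRHL2. Keratins KRT18 (0.79 ± 0.04) and KRT8 (0.59 ± 0.04), at 164 and 132 CPM in DMSO, rose, and RAB25 (2.10 ± 0.66) and CLDN3 (1.43 ± 0.53) rose at levels under 1 CPM. KRT8 fell short of the fold limit under DESeq2 (0.58), with no count filter (0.58), without DMSO replicate 1 (0.57) and without CBL0137 replicate 2 (0.55), RAB25 lost its call without DMSO replicate 1 (2.09), DMSO replicate 2 (2.10) or CBL0137 replicate 2 (1.80), and CLDN3 without DMSO replicate 2 (0.92), CBL0137 replicate 1 (1.31) or CBL0137 replicate 2 (1.53). Camera called the list higher (median 0.75, adjusted p = 4.8e-04; adjusted p = 0.213 with an estimated correlation). Of 3 tested blood cell markers, ITGAM rose (0.72 ± 0.18), 0 fell and 2 were not called, among them CD14 at 1.19 ± 0.57, with 1 rise adjusted over the list alone, while DESeq2 called 0 (ITGAM at 0.72, adjusted p = 0.0507) and limma-voom 1. Of 12 neuronal markers, INA rose (0.68 ± 0.10), 0 fell and 11 were not called, with 1 rise adjusted over the list alone; UCHL1 measured -0.50 ± 0.03, SYT1 -0.42 ± 0.04 and GAP43 0.46 ± 0.10, and INA fell short without DMSO replicate 1 (0.54). Of 15 mitochondrially encoded genes, 0 were called by edgeR, DESeq2 or limma-voom, and 0 adjusted over the list alone, with 10 at an unadjusted p under 0.05, and MT-RNR2 stood at -0.29 ± 0.02, MT-ND1 at 0.34 ± 0.03, MT-CYB at 0.12 ± 0.03 and MT-ND4 at -0.10 ± 0.03. Camera called none of the blood, neuronal and mitochondrial lists (adjusted p = 0.465, 0.786 and 0.786), although fry called the blood list (0.0302, range over alternatives 0.0302 to 0.903) and the mitochondrial list was higher with the abundance trend removed (0.0214, range 0.0214 to 0.889).

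**Figure D3:**
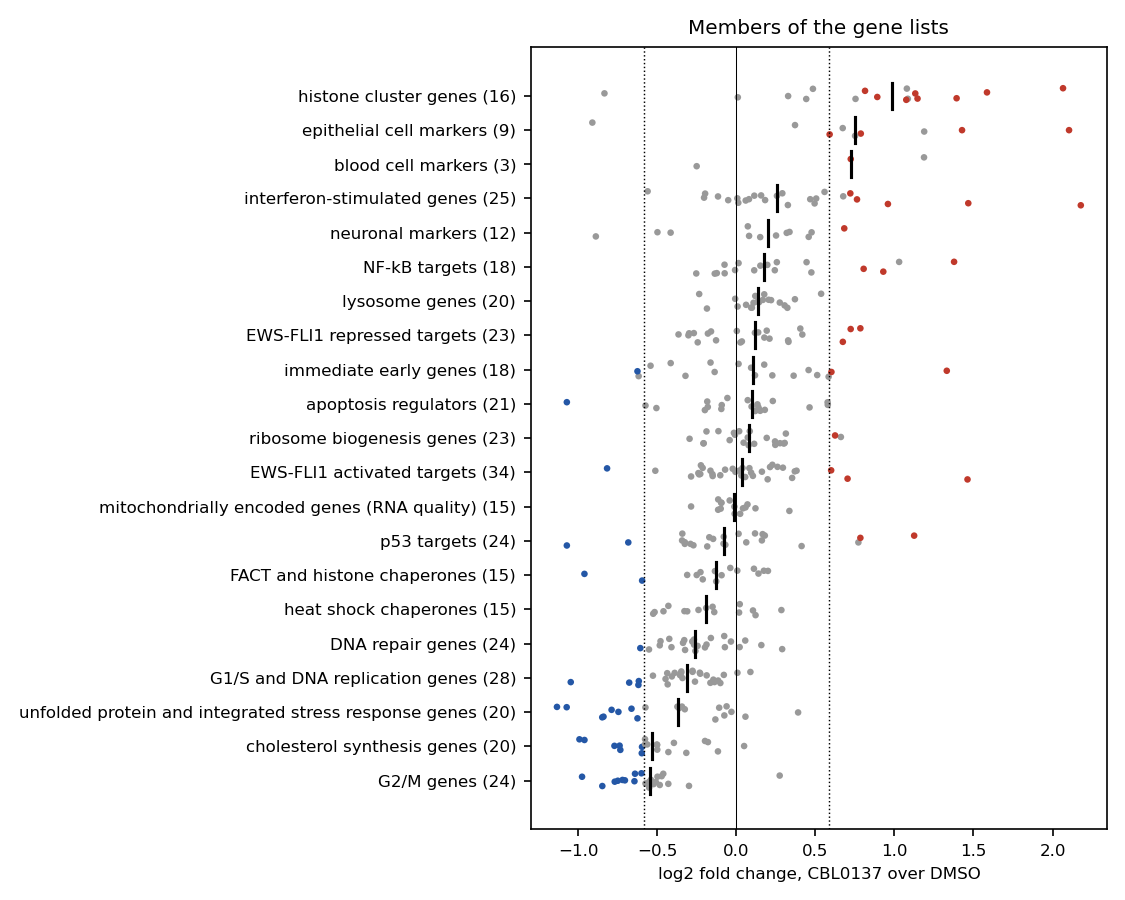
Log2 fold change of CBL0137 over DMSO for each tested member of the 21 gene lists (number tested in brackets), with members called higher in red, called lower in blue and not called in grey; black bars are list medians and dotted lines a 1.5-fold change. Medians run from -0.55 for G2/M genes to 0.98 for histone genes, and the mitochondrial list turns from lower to higher under library size alone.

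Among called genes with a mean of at least 5 CPM and conditions that did not overlap, the largest rise was in ABCC3, an efflux transporter (chromosome 17, 48712138 to 48769614), from 1.98 ± 0.229 to 9.72 ± 2.43 CPM (2.30 ± 0.20). It was followed by LRRC55, an auxiliary subunit of BK potassium channels (2.16 ± 0.08), COL6A3 (chromosome 2, 238232646 to 238322971; 2.06 ± 0.07), the membrane skeleton adaptor ANK1 (2.0 ± 0.18), the interleukin-7 receptor IL7R (1.88 ± 0.12) and the retinol transporter STRA6 (1.80 ± 0.12). KRT17P1 (1.80 ± 0.15), C1QTNF1 (1.80 ± 0.08), GIPC3 (1.73 ± 0.15) and IL4I1 (1.61 ± 0.11) completed the 10 largest rises. KRT17P1 is a pseudogene whose reads can be shared with KRT17, so its value is uncertain. The largest fall was in the secreted phospholipase PLA2G3 (chromosome 22, 31530793 to 31536494), from 13.7 ± 1.54 to 4.06 ± 1.4 CPM (-1.77 ± 0.17). ARHGAP33 (-1.48 ± 0.09), the thioredoxin-binding protein TXNIP (-1.42 ± 0.07), the neurotrophin receptor NTRK2 (-1.41 ± 0.13), mitochondrial PEP carboxykinase PCK2 (-1.34 ± 0.09) and the cystine transporter SLC7A11 (-1.21 ± 0.06) came next. MEST (-1.18 ± 0.15), the threonine pathway enzyme GCAT (-1.18 ± 0.10), FAM72D (-1.12 ± 0.14) and the lipid droplet protein HILPDA (-1.12 ± 0.07) completed the 10 largest falls, and FAM72D is uncertain because its near-identical paralogs can share its reads. The edgeR adjusted p of these 20 genes ran from 4.9e-17 to 7.5e-07.

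The 2 conditions did not overlap in 11575 genes, 66.9% of those tested, against 33.3% by chance for 2 libraries against 2. Among protein-coding genes 852 were called higher and 368 lower, and among lncRNA genes 247 and 59. Without the fold limit 6314 genes passed, 3022 higher and 3292 lower, so the share of higher genes was 47.9% there and 71.6% among the called genes.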

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

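The abundance-trend test was chosen after its result was seen, and the other alternatives were planned. The main count of 1663 called genes stayed within 1.5 times under the other normalisations, count filters and limma-voom (1518 to 1808 genes). These settings kept 85.7% to 99.8% of the main calls. With a replicate left out more of the main calls were lost than under these settings, although the main count stayed within the same bound. It moved under DESeq2 (919, with 593 higher), with no fold limit (6314, with 3022 higher and 3292 lower), at a fold above 2 (736, with 605 and 131), with glmTreat (399, with 295 and 104), which by construction asks for more than a 1.5-fold change, and on the deposited FPKM (577, with 388 and 189). The cause of the DESeq2 difference was not tested. Of the 1663 called genes, 926 passed the FPKM filter, so the others could not be called on FPKM. The pseudocount of 1 also shrinks the fold change of genes with low FPKM. How much each adds to the FPKM difference was not tested. On FPKM, 14 of 926 called genes present in both tables went the other way, and the deposited FPKM per count of 1 library was off by over 1.5-fold in 589 of 11339 genes. The replicate block, with the replicate number as a term, called 1576 genes. The deviations of same-numbered libraries had a correlation of -1e-04, so no effect shared by same-numbered libraries was seen. Noise in weak genes could hide a small one, and the labels do not say whether those libraries were made together. The replicate block changed the call of no list.

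Of 58 called genes named by the rule, 26 kept direction and call under all 16 alternatives. These alternatives include the fold limit of 2, under which every gene changed less than 2-fold loses its call by construction. AURKB (-0.98) and MKI67 (-0.72) are examples. The stricter glmTreat is also among them, so the 26 do not measure dependence on processing alone. SUPT16H turned to 0.01 under upper-quartile factors, 0.024 under library size alone and 0.037 on FPKM. FLI1 turned to -0.78 on FPKM and ranged from -0.028 to 0.094 with a replicate left out, and NAP1L1 turned to 0.354 on FPKM. On FPKM both turns rest on 1 library whose value departs from its counts. NAP1L1 had 127 FPKM in CBL0137 replicate 1 against 48.6 to 70.7 in the others, though its 11290 counts there were the fewest of the 4, and FLI1 had 2.79 in CBL0137 replicate 2 against 10.4 to 11.8, with 1618 counts there. Why those values depart was not tested. SUPT16H and FLI1 are within 2 standard errors of 0.

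With an estimated correlation, camera's adjusted p was 0.366 for FACT and histone chaperones, 0.213 for NF-kB targets, heat shock chaperones, histone genes and epithelial markers, 0.37 for interferon-stimulated genes, 0.11 for G2/M and cholesterol genes, 0.21 for G1/S genes, 0.305 for DNA repair, 0.143 for the stress response list and 0.328 for lysosome genes. All 12 lists keep their direction but lose their call there, and a correlation estimated from 4 libraries is itself imprecise. Fry gave 0.00299 for p53 targets and 0.743 for apoptosis regulators, both with a lower direction. It gave 0.0591 for interferon-stimulated genes and 0.0302 for blood markers, both with a higher direction. With the abundance trend removed, the adjusted p was 0.172 for FACT and histone chaperones and for heat shock chaperones, 0.0214 for EWS-FLI1 activated targets, 0.0269 for repressed targets and 0.00984 for ribosome biogenesis genes, the last 3 toward higher levels. The mitochondrial list turned higher there (0.0214) and under library size alone (0.558), and ranged from 0.391 to 0.889 with a replicate left out, turning without CBL0137 replicate 2. EWS-FLI1 repressed targets passed under library size alone (0.046) and ranged from 0.0148 to 0.202 with a replicate left out, passing without CBL0137 replicate 1. Apoptosis regulators ranged from 0.816 to 0.986 and turned lower without DMSO replicate 1, DMSO replicate 2 or CBL0137 replicate 1. The cause of the changes under the other settings was not tested.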

Other observations

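The families in the next 2 paragraphs, and the genes named from them, were chosen after the values were seen, as were, further on, the lists of ATF4 targets and of chaperones of the endoplasmic reticulum (after the stress response list was seen to fall), the tests of genomic DNA and of RNA from other cells, the removal of the GC trend from the abundance pattern and the errors by GC quintile. Among 15 such families, tested together with those 2 lists as 17 sets, collagens had 13 of 31 tested genes higher and 0 lower at the limits used in the report (median log2 fold change 0.47, camera adjusted p = 3.9e-23; adjusted p = 0.102 with an estimated correlation). They included COL6A3 (2.06 ± 0.07 SE), COL6A1 (0.89 ± 0.04), COL5A1 (0.86 ± 0.04) and COL1A1 (0.79 ± 0.04), chains of collagens VI, V and I. Of 32 interleukins and interleukin receptors, 9 were higher and 0 lower, among them IL1B (1.20 ± 0.08), IL33 (0.80 ± 0.08) and IL32 (0.62 ± 0.06), with an adjusted p of 8.5e-06 and of 0.187 with an estimated correlation. Of 15 matrix metalloproteinases, 1 was higher, MMP9, which rose from 68.9 to 208 CPM (1.6 ± 0.05). The 2 called lower were MMP1, from 1490 to 974 CPM (-0.62 ± 0.03), and MMP16 (-0.61 ± 0.12). Camera placed the family higher (median 0.23, adjusted p = 0.0297), with an adjusted p of 0.308 with an estimated correlation. Of 19 calcium channel genes 4 were higher, CACNG7 (3.27 ± 0.31), CACNG8 (1.17 ± 0.09), CACNA1A (0.72 ± 0.13) and CACNA1G (0.65 ± 0.06), and 0 were lower.

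On the falling side, 65 of 80 cytosolic ribosomal protein genes were lower at an edgeR adjusted p under 0.05, although 3 passed the fold limit, RPL9 (-0.72 ± 0.04), RPL3 (-0.65 ± 0.04) and RPS13 (-0.59 ± 0.04), with a median of -0.30 (camera adjusted p = 1.1e-36; adjusted p = 0.0994 with an estimated correlation). Of 17 tubulin genes 5 fell, including TUBB from 1820 to 1020 CPM (-0.84 ± 0.03). Of 22 centromere protein genes 3 fell, CENPI (-0.96 ± 0.07), CENPA (-0.78 ± 0.07) and CENPX (-0.78 ± 0.07). FASN, which makes palmitate, fell from 1380 to 752 CPM (-0.88 ± 0.03), and the acetyl-CoA synthetase ACSS2 (-0.68 ± 0.07) also fell among 12 fatty acid synthesis genes. Among 17 glycolysis genes ALDOC (-1.0 ± 0.07), HK2 (-0.67 ± 0.05) and ENO2 (-0.62 ± 0.04) fell. Of 17 NRF2 targets, SLC7A11 and OSGIN1 (-1.85 ± 0.23) fell and TXNRD1 measured -0.55 ± 0.04. The counts of higher and lower genes were 5 and 1 among 9 keratins, 4 and 7 among 37 kinesins, 9 and 2 among 47 potassium channels, 4 and 1 among 16 ephrins and their receptors, and 2 and 0 among 10 S100 proteins.

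Called rises were concentrated among weakly expressed genes, with 759 higher and 182 lower below a mean of 5 CPM (80.7% higher) and 432 higher and 290 lower above it (59.8%). The median log2 fold change of protein-coding genes was 0.23 below that level and -0.03 above it, a difference of 0.27 that stayed between 0.27 and 0.30 with any replicate left out. Genomic DNA in the CBL0137 libraries is argued against as the source of the called weak rises. The gain of reads assigned to no gene, spread over the genome outside exons, predicts a median of 0.536% of the gain of these rises. Such reads can include introns. RNA from epithelial or blood cells is argued against as well, for the called weak rises alone. Of 8 transcripts abundant in such cells, the highest gain plus 2 SE was 0.641 CPM (CD14, 0.259 CPM in DMSO and 0.617 in CBL0137). The called weak rises had a median gain of 1.19 and a lower quartile of 0.764 CPM. These genes were picked because they rose, so neither test covers the median of 0.23 over all weak protein-coding genes. In DMSO and CBL0137, EPCAM stood at 0.451 and 0.256, CDH1 at 0.0645 and 0.0877, PTPRC at 0.0431 and 0 and LYZ at 0.0648 and 0.0488. Of the other markers, however, CLDN3, RAB25 and ITGAM gained 0.557, 0.465 and 2.63 CPM, and KRT8 and KRT18, already high in DMSO, 73.8 and 128. The values of these transcripts and markers are CPM over all gene counts without TMM scaling, while the gains of the weak rises are after it. After TMM scaling KRT8 rose from 132 to 199 CPM and KRT18 from 164 to 282 CPM. GC bias is argued against as the whole cause, since the difference was 0.223 (bootstrap SE 0.012) once the GC trend was removed and lay above 0 by over 2 SE in each of 5 GC quintiles, at 0.103 (SE 0.036) in the lowest, which is within its error of the bound of 0.1 set beforehand, and 0.193 to 0.315 in the others, so a part played by GC stays open. Release of rarely transcribed genes by CBL0137 may contribute but stays open, since among lncRNA genes the difference was 0.026.

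The fall of the integrated stress response list may reflect lower ATF4 output. A separate list of 24 tested ATF4 targets, including MTHFD2, SLC7A5 and several aminoacyl-tRNA synthetases, had a median log2 fold change of -0.453 (camera adjusted p = 3.1e-23 over the 17 sets; adjusted p = 0.0994 with an estimated correlation), with 7 called lower and 0 higher, against -0.05 for 15 chaperones of the endoplasmic reticulum. GC bias is argued against, since the median of the stress response list was -0.489 after the GC trend was removed. Of the 20 members of that list, 18 lay below 0 and 2 above it. DDIT3, noted after its value was seen, was among those above (0.39, edgeR adjusted p = 0.0096) but inside the fold limit. Cytosolic ribosomal protein genes also had a lower median (-0.30), so the ATF4 targets alone do not tell lower ATF4 output from a wider fall.

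Called genes of one direction lay next to each other more often than chance. Among 13227 neighbouring pairs of tested genes that do not overlap, 174 were called in the same direction (148 higher and 26 lower), against a mean of 78.4 and a highest value of 105 when calls were permuted 1000 times among genes of like abundance and GC content. Reads shared between overlapping genes and GC content shared by neighbours are therefore argued against as the whole cause, the share of permutations with as many pairs being 0.001, the smallest that 1000 permutations can give, and 150 pairs remained when genes of 1 symbol family were left out (mean 69.9). A candidate explanation is a regional change along the chromosome under CBL0137, with transcription running from 1 gene into the next as an untested alternative. The permutations break every link between neighbours, so they cannot tell either from other reasons for neighbours to change together. Of 35 runs of 3 or more neighbouring genes called one way, overlapping genes included, 32 rose and 3 fell. Because 71.6% of all called genes were higher, more rising than falling pairs and runs are expected by chance. The number and direction of runs were not tested. A run that fell, singled out after its values were seen, holds TTC12 (-2.34 ± 0.70), ANKK1 (-1.93 ± 0.39) and DRD2 (-1.64 ± 0.21). It lies on chromosome 11 from 113185301 to 113346413 in GRCh37, next to NCAM1 (-0.37 ± 0.12), which was not called. TTC12 is near the floor, with 13 and 14 counts in DMSO replicates 1 and 2 and 1 and 4 in those of CBL0137. ANKK1 had 62 and 41 against 18 and 8, and DRD2 151 and 131 against 35 and 53.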
